A study of Mus musculus with 6 samples.

How the data were processed

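Striatal RNA was measured in 6 libraries from mice of the Q113 DRPLA line at 22 weeks of age. These mice carry an expanded CAG repeat as a model of dentatorubral-pallidoluysian atrophy, a neurodegenerative disease caused by a polyglutamine expansion in atrophin-1. Of the 6 libraries, 3 are labelled as treated with naphthyridine-azaquinolone (NA), a small molecule that binds CAG repeat structures, and 3 with phosphate-buffered saline (PBS). Libraries were made from total RNA with a stranded Illumina mRNA kit, per the labels' protocols. Dose, route and length of treatment are not given in the sources used here.

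The authors deposited 1 table per library, with 34406 loci and 1 value per locus. The values were taken to be FPKM, fragments scaled to locus length and library size, although neither the labels nor the file headers name the unit as deposited. That reading rests on Cufflinks being named per the submitters' processing notes, on file headers and locus identifiers of the kind Cufflinks writes, and on sums between 502273 and 575028 per library, which are too low for fragment counts. The submitters' processing notes name FastQC, TopHat2 2.0.13, Cufflinks 2.2.1 and the mouse genome build GRCm38. The gene annotation, the Cufflinks program that wrote the tables and the scaling between libraries are not given in the sources used here. FPKM values depend on the total and on the length assigned to a locus, so a few very abundant loci can lower all others in a library, and short loci can swing between 0 and high values.

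The tables identify loci only by numbers of the form XLOC_000001, and the files do not pair these with gene names or positions. Of the 34406 identifiers, 0 were found in the reference tables. No locus was therefore assigned to a gene, chromosome or exon. Atn1, the mouse counterpart of the gene behind DRPLA, and 40 lists of striatal, glial, stress and repair genes had been fixed before the data were examined and were not analysed here. The rule for loci to be named considered, per direction, those whose NA and PBS libraries did not overlap. It took first those past the adjusted threshold with the largest fold changes and filled the remaining places by smallest unadjusted p. The number per direction was set higher than 2, and identifiers without a gene name were to be left uncited. The 4 loci given, 2 per direction by smallest unadjusted p, are therefore an exception made after the values were seen.

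Whole fragments leave steps among low FPKM values, since a locus with p fragments in one library and q in another has a ratio of p/q times a constant. The constant was estimated for each library against NA replicate 1 from loci under 0.2 FPKM in both libraries, with 95% intervals from 200 bootstrap draws. Estimates were read off a grid of fixed steps and the draws resampled loci. An interval can therefore have no width and does not cover other sources of error. On simulated libraries the estimate was within 0.003 log2 units of the truth in each of 5 libraries. This gives relative depth only if the values were scaled to the number of fragments in each library, which the sources do not state. Absolute depth is unknown, so no counting intervals or detection limits are given, and a value of 0 is described as listed at 0.

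The test was limma's moderated test (limma 3.58.1, R 4.3.3) with a mean-variance trend on log2(FPKM + 0.5), for the 14637 loci with a mean of at least 1 FPKM over the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low loci, and are coded NA minus PBS. The fit was tested on simulated data with 200 changed loci. When changes were added to the deposited values themselves, 73 of 100 loci changed 2-fold and 93 of 100 changed 4-fold were called, with 3 other loci called. With 200 changed loci the adjusted threshold is easier to reach than with a few. Comparisons of whole libraries used exact permutation tests over the 10 ways to split 6 libraries into 3 and 3, whose smallest possible p is 0.1. The labels give 3 samples per treatment and do not number the animals, so p-values measure the spread between these samples.

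The labels number the libraries 1 to 3 in both groups, without saying what a number shares. Deviations from the group means correlated at 0.14, 0.49 and 0.27 between NA and PBS libraries numbered 1, 2 and 3. All lie above 0.1, the level set beforehand for treating numbers as pairs, although NA replicate 3 correlated more with PBS replicate 1 (0.35). A fit with the replicate number as a block is therefore given beside the main one where it moves a count by over 1.5 times. No 2 libraries were duplicates, as no pair shared over 1 identical nonzero value.

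The alternatives were other pseudocounts, filters, scalings and variance models, sample weights, the replicate block and leaving out each library, 16 in all, and 3 more were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.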

Results

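Expression was measured at 34406 loci in 6 striatal libraries from Q113 DRPLA mice, 3 from treatment with the CAG repeat-binding molecule naphthyridine-azaquinolone (NA) and 3 from PBS. Each library listed between 7272 and 7558 loci at 0. Loci with at least 1 FPKM numbered 14537 ± 129 (SD, n = 3) under NA and 14652 ± 122 (SD, n = 3) under PBS. The upper quartile of FPKM was 7.63 ± 0.090 (SD, n = 3) under NA and 7.66 ± 0.067 (SD, n = 3) under PBS. Relative to NA replicate 1, the depth was 0.877 (95% interval 0.874 to 0.883) in NA replicate 2 and 1.04 (1.04 to 1.04) in NA replicate 3. It was 1.07 (1.07 to 1.07), 0.832 (0.826 to 0.835) and 0.804 (0.804 to 0.804) in PBS replicates 1, 2 and 3. The narrow intervals reflect the grid of the estimate and the resampling of loci. The 3 most abundant loci made up 9.38% of the summed FPKM in NA replicate 3 and between 16.2% and 19.4% in the other libraries.

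The comparison of NA with PBS addresses which transcripts in the DRPLA striatum differ after treatment. No locus was called higher or lower in NA. Of 14637 loci tested, 0 were higher and 0 were lower at an adjusted p under 0.05 with limma, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 281 loci (1.92%), of which 114 had higher and 167 lower means in NA, while 5% of the tested loci would be 732. With the replicate number as a block, limma again called 0 loci in either direction, the smallest adjusted p was 0.321, and 652 loci (4.45%) had an unadjusted p under 0.05, including 242 of the 281. Leaving out NA replicate 2 gave 1 locus called higher, and leaving out NA replicate 3 raised the count at an unadjusted p under 0.05 to 423.

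Most loci lay close to the same level in both treatments. The median absolute log2 fold change was 0.07, with a median standard error of 0.12 (n = 3 per group), and the median log2 fold change was 0.01. For 13578 loci (92.8%) the 95% interval of the difference lay within 2-fold in either direction, and for 11518 (78.7%) within 1.5-fold. Precision was lowest at low levels. The median standard error was 0.17 for 4418 loci between 1 and 5 FPKM, 0.10 for 5703 loci between 5 and 20 FPKM and 0.09 each for 3762 loci between 20 and 100 FPKM and 754 loci at 100 FPKM or more. The share of loci with a 2-fold difference was 1.47%, 0.30%, 0.24% and 1.06% in the same order. Means differed by at least 2-fold at 99 loci, 34 higher and 65 lower in NA, none of them past the adjusted threshold in limma. This count was 34 with a mean of at least 5 FPKM, 66 and 157 with pseudocounts of 1 and 0.1, and 169 without NA replicate 3. The libraries of the 2 groups did not overlap at 41 of these 99 loci, and 25 of the 99 were listed at 0 in at least 1 library. Over all tested loci the groups did not overlap at 805 (5.50%). Other splits of the 6 libraries into 3 and 3 gave 632 to 3766 such loci. The 3 of them that part all replicate numbers gave 632, 704 and 873.

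The 4 loci given had the smallest unadjusted p of their direction, 2 lower and 2 higher, among those whose groups did not overlap. None passed the adjusted threshold, and their separation beyond the spread within groups follows from this choice. XLOC_009416 was at 4.10 ± 0.36 FPKM (SD, n = 3) in NA and 7.31 ± 0.42 FPKM (SD, n = 3) in PBS. Its log2 fold change was -0.76 (SE 0.10, unadjusted p = 0.000141, adjusted p = 0.9999, limma). XLOC_006810 was at 1.77 ± 0.44 FPKM (SD, n = 3) in NA and 4.51 ± 0.47 FPKM (SD, n = 3) in PBS. Its log2 fold change was -1.16 (SE 0.17, unadjusted p = 0.000324, adjusted p = 0.9999, limma). XLOC_028886 was at 3.94 ± 0.76 FPKM (SD, n = 3) in NA and 1.27 ± 0.66 FPKM (SD, n = 3) in PBS. Its log2 fold change was 1.37 (SE 0.27, unadjusted p = 0.00179, adjusted p = 0.9999, limma). XLOC_025941 was the most abundant of the 4, at 39.0 ± 5.7 FPKM (SD, n = 3) in NA and 22.7 ± 4.4 FPKM (SD, n = 3) in PBS. Its log2 fold change was 0.78 (SE 0.17, unadjusted p = 0.00349, adjusted p = 0.9999, limma). With the replicate number as a block in limma, the unadjusted p of the 4 loci were 0.000691, 0.000234, 0.00023 and 0.00568, in the order given. The adjusted p were 0.482, 0.357, 0.357 and 0.964. The files pair none of these identifiers with a gene or a position.

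**Figure D1:**
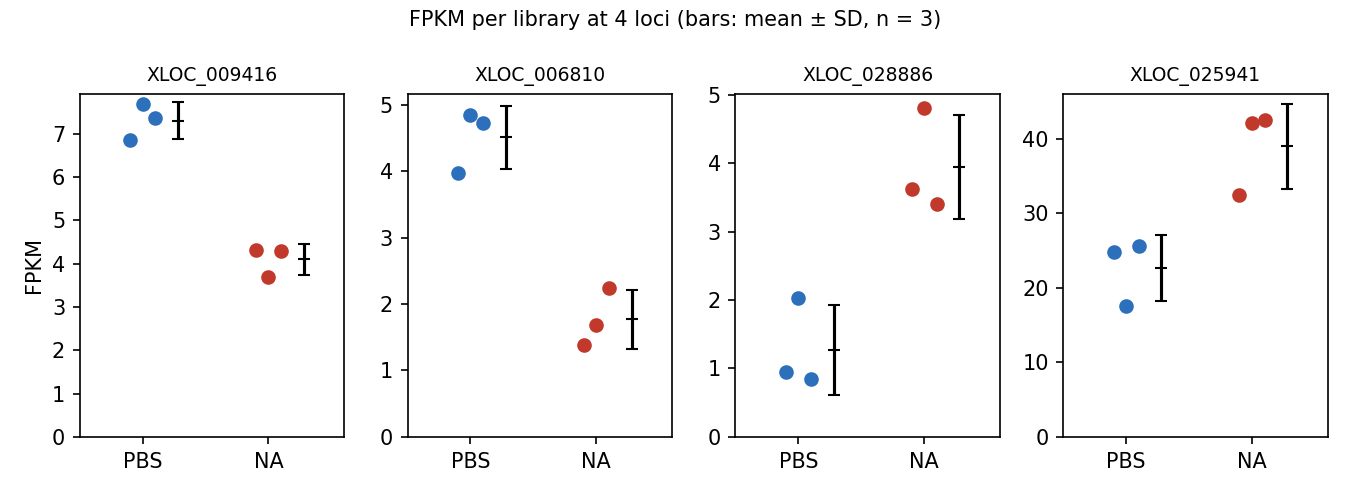
FPKM (linear axes from 0) of each PBS library (blue) and NA library (red) at the 4 loci given by identifier, with mean ± SD, n = 3 per group. The loci were selected so that the 3 NA libraries lie apart from the 3 PBS libraries, and the means and SDs are given in the text.

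Libraries were about as alike within a treatment as between treatments, and the replicate number moved the order of these values. Across loci, Pearson's r of log2(FPKM + 0.5) averaged 0.974 ± 0.0086 (SD) over the 6 pairs within a treatment and 0.976 ± 0.0086 (SD) over the 9 pairs between treatments. Of these 9, the 3 pairs with the same replicate number averaged 0.981 ± 0.0005 (SD) and the 6 with different numbers averaged 0.973 ± 0.0096 (SD), so without same-number pairs the mean between treatments lay below that within. However, the most alike pairs had different numbers, NA replicate 3 with PBS replicate 1 (0.984) and NA replicate 1 with PBS replicate 2 (0.983). The lowest pairs between treatments were NA replicate 2 with PBS replicate 1 (0.961) and with PBS replicate 3 (0.965). Loci are not independent replicates, so these values describe the libraries. The difference in mean r of -0.00188, within minus between treatments, was reached by 6 of the 10 splits, the real one included (one-sided exact permutation p = 0.6). The treatment labels took up 16.4% of the variance among the 6 libraries, against 13.5% to 36.1% for the other splits (one-sided exact permutation p = 0.6). Among the 4 splits that part all 3 replicate numbers, the treatment ranked first on both measures. It had 16.4% of the variance against 13.5% to 15.8% and a difference in r of -0.00188 against -0.00336 to -0.00219. The 2 measures put the 10 splits in the same order, so they are not separate results. The treatment did not rank first on the first principal component. There the group means differed by 8.37, against 17.7, 5.88 and 3.45 in the other splits of this kind. The smallest p that 4 splits allow is 0.25, and the values by replicate number were chosen after the result had been seen. The first principal component held 44.3% of the variance. NA replicate 2 scored 37.9 on it and NA replicate 3 scored -24.7, the extremes of the 6 libraries. PBS replicate 2 scored 16.5, NA replicate 1 scored -0.60, PBS replicate 3 scored -10.7 and PBS replicate 1 scored -18.3.

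**Figure D2:**
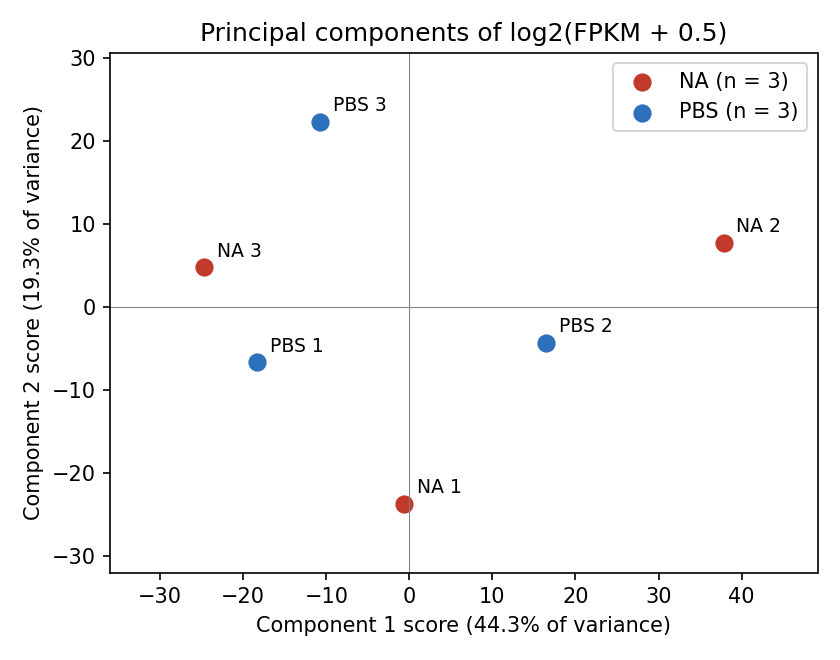
Scores of the 6 libraries on the first and second principal components of log2(FPKM + 0.5), in log2 units, with NA in red and PBS in blue (n = 3 each). NA replicates 2 and 3 lie at the ends of component 1, at 37.9 and -24.7, with the PBS libraries between them.

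NA replicate 2 stood apart in loci of both directions. It lay at least 4-fold above the median of the other libraries at 32 loci and at least 4-fold below it at 49, 81 in all, against 26 to 37 in each other library. Leaving out loci listed at 0 in any library left 29 higher and 41 lower loci, with a median level of 3.58 and 16.1 FPKM. PBS replicate 2 moved the same way. It lay above the median of the libraries other than NA replicate 2 at 27 of the 29 higher loci (median log2 ratio 1.21) and below it at 39 of the 41 lower loci (median log2 ratio -1.14). NA replicate 1 lay above at 24 of the 29 (0.70) and below at 33 of the 41 (-0.45). Relative to a median of 5 libraries, 2 lie above and 2 below at each locus, so the places of the remaining libraries are limited by these. These loci were chosen on NA replicate 2 after the components had been seen.

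**Figure D3:**
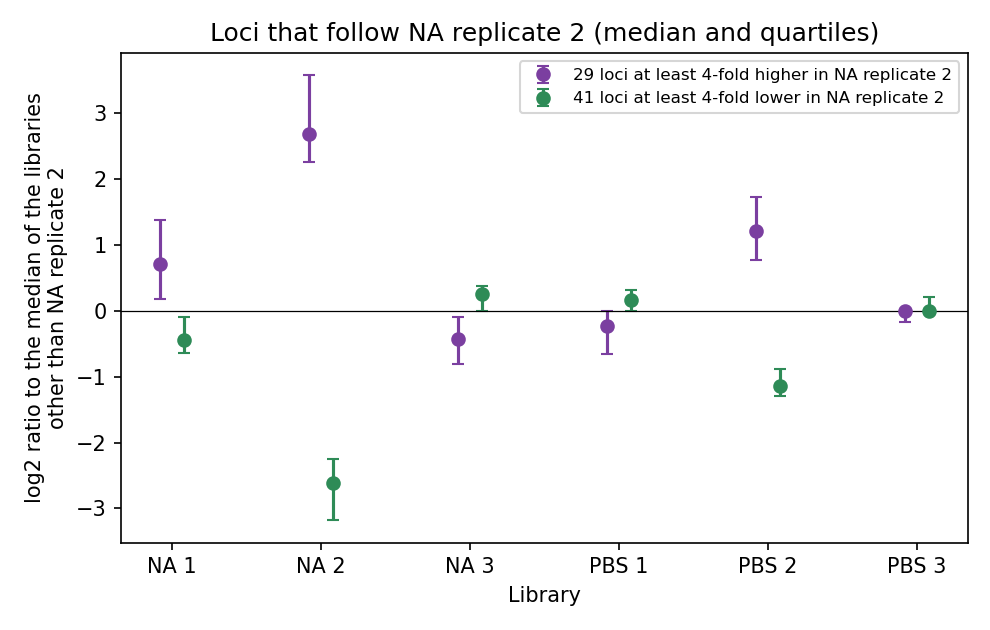
Median and quartiles, over loci, of the log2 ratio of each library to the median of the 5 libraries other than NA replicate 2, for the 29 loci at least 4-fold higher (purple) and the 41 at least 4-fold lower (green) in that library. PBS replicate 2 follows NA replicate 2 in both sets, at 1.21 and -1.14.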

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

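Of the values given here, those for the first residual component as a covariate, for leaving out 2 libraries together and for leaving out loci listed at 0 were chosen after the data had been seen. With limma, 0 loci were called higher in 17 of 19 alternatives and 0 lower in 18 of 19. Leaving out each library in turn gave 0 to 1 called higher, the 1 arising without NA replicate 2 (adjusted p = 0.00345), and 0 called lower. Leaving out NA replicate 2 and PBS replicate 2 together gave 2 called higher and 2 called lower (smallest adjusted p = 0.0336). None of the called loci was among the 4 given by identifier. The count at an unadjusted p under 0.05, 281 with the chosen settings, was 893 of 28935 loci with no filter on low values and 126 of 10219 with a mean of at least 5 FPKM, where the number of loci tested also changed. It was 437 with sample weights, 652 with the replicate block and 752 with the first residual component as a covariate. The covariate raised the count in all 10 splits of the libraries, to 531 to 3602 in the 9 others, so its rise says nothing of the treatment. Leaving out each library in turn gave 200 to 423, with 423 without NA replicate 3. The block changed no adjusted call. Loci with a difference of at least 2-fold numbered 66 with a pseudocount of 1, 157 with a pseudocount of 0.1, 34 of 10219 loci with a mean of at least 5 FPKM and 169 without NA replicate 3, against 99. The 4 loci given by identifier stayed short of the adjusted threshold in every alternative that tested them. They also kept their direction. Since they were selected for groups that do not overlap, leaving out a library or changing the pseudocount could not reverse it. Component 1 held 39.3% to 52.4% of the variance over the alternatives that change the values or the libraries. The alternatives planned for counts did not apply to FPKM, and those for gene lists and for Atn1 were not run because the identifiers have no gene names. Absolute depth is unknown, so how far counting error limits the low loci is not known either.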

Other observations

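The counts of splits were planned before the data were examined, and the other tests in this part were chosen after the result had been seen.

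Loci at an unadjusted p under 0.05 leaned in opposite directions at low and high levels. Between 1 and 5 FPKM, 121 of the 158 such loci had lower means in NA (76.6%), whereas at 100 FPKM or more 10 of 10 had higher means in NA. Among the 9 other splits of the libraries, the share of low loci in the larger direction reached 74.5%, and 10 splits are too few for a share under 0.05. The 10 loci at 100 FPKM or more, of 754 tested at that level, were not compared with other splits. None of these loci passed the adjusted threshold with limma. Of the 99 loci that differed by at least 2-fold, 25 were listed at 0 in at least 1 library. Listed at 0 in at least 1 library and at 20 FPKM or more in another were 16 loci, 14 of them among these 25, and whether zeros are failed estimates was not tested.

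A count of 0 called loci is reached by any split, here 10 of 10 splits of the 6 libraries into 3 and 3 with 1 call as the highest of the others, so it says nothing about chance. The count of 281 loci at an unadjusted p under 0.05 was reached by 7 of the 10 splits, which are too few for a share under 0.05. The highest other count was 2673, from NA replicates 1 and 2 with PBS replicate 2 against the rest, which points to a structure of the libraries other than the treatment. Among the 4 splits that part all 3 replicate numbers, as the treatment does, the treatment gave 281 loci without the block, against 159, 191 and 265, and 652 under the replicate block, against 441, 587 and 1112.

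NA replicate 2 lay apart on component 1, with PBS replicate 2 part of the way there. One scaling factor for the library would move its loci one way, but 60.5% of the loci 4-fold away lay in the larger direction. Of the 2 libraries of lower relative depth only 1, PBS replicate 3, scored under 0 on the component, where the rule asked for 2. However, PBS replicates 2 and 3 lay 4-fold away at 30 and 29 loci, against 81 in NA replicate 2. Their scores were 16.5 and -10.7, against 37.9. On the other hand, the libraries of highest relative depth, PBS replicate 1 (1.07) and NA replicate 3 (1.04), had the lowest scores, -18.3 and -24.7. PBS replicate 2 also shared part of the pattern. Lower depth alone would not place NA replicate 2 beyond 2 shallower libraries, but under the rule a part of depth stays open. A part of the treatment stays open, since the mean scores of NA and PBS differed by 8.37 and 7 of the 10 splits gave as much, too few splits to decide. One other tissue mixed in at 1 share per library would place all loci of a library at the same fraction of the way. That fraction is counted from NA replicate 3 to NA replicate 2. Its medians in the 29 higher and 41 lower loci differed by 0.453 in PBS replicate 2 and 0.293 in NA replicate 1. They differed by 0.152 in PBS replicate 3 and 0.114 in PBS replicate 1. The 95% bootstrap interval for PBS replicate 2, 0.383 to 0.506, came from resampling loci, so it does not measure the spread between libraries. Libraries simulated from 2 sources gave 0.030, but with noise independent between loci and the observed NA replicates 2 and 3 as sources. The loci were chosen as the farthest away in NA replicate 2, so this explanation stays open too. Several tissues or cell types in varying shares, differences between individual mice and RNA quality may each account for the pattern and were not tested. Markers of tissues or cell types could not be examined, since the loci have no gene names.

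Deviations from the group means were compared between tested loci that follow each other in the order of identifiers, whose numbers can lie several apart. These correlated at 0.055 on average, above the highest of 1000 shuffled orders, 0.016 (one-sided permutation p = 0.001, the smallest that 1000 orders can give). At 2, 5 and 20 steps, counted in tested loci, they correlated at 0.023, 0.012 and 0.001. No explanation of this was tested.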
